A study of Homo sapiens with 11 samples.

How the data were processed

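The series measured expression on 3 two-colour 44K arrays and histone marks on 8 two-colour promoter tiling arrays in the cell lines HCT116 and DKO. The groups were DAC versus mock, TSA versus mock and DKO versus HCT116 for expression, 1 array each, and H3K4me2 and H3K27me3 in HCT116 and in DKO for ChIP-chip, 2 arrays each. The DAC array is called DAC in its title and 5-AZA in its source label, and DAC is used here. The series design text speaks of duplicates, but both arrays of a ChIP group came from different designs with 0 probe names in common, so they were taken as the parts of an array set and not as replicates. No replicates, dye swap or second batch exist among these arrays, and the IgG control named in the design text was not analysed here.

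Spot intensity values were made with Agilent Feature Extraction, per the file headers: version 9.1.1.1 with linear and LOWESS dye normalization for the DKO expression array, and version 9.1.3.1 with linear dye normalization for 7 ChIP arrays. The expression scanner file also holds the log10 ratio of Cy5 over Cy3 after background subtraction and dye normalization, per the file headers. The deposited value tables hold log2 ratios of Cy5 over Cy3. For ChIP the authors made them with ChIP Analytics 1.3 (median blank subtraction, inter-array median and dye-bias median normalization), per the series design text. For expression the submitters' processing notes name limma, without a version, and the scale and recipe were read from the values. The deposited DKO column matched the log2 ratio of median red over median green with limma loess and no background correction (Pearson r 0.9999 across spots) after its values were moved by 1 row from just before its first blank row on, which moved 43227 of 43376 non-control spots. As deposited the correlation was 0.0016. The DAC and TSA columns had matching spots of the same probe in their own rows and were read as deposited; their scale is inferred from the DKO column and the dye labels. Column medians were 0.00598 for DAC, 0.0108 for TSA and 0.00402 for DKO. The genome build of the promoter annotation is not given in the sources used here, so no coordinates are printed.

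For DKO versus HCT116 the main values came from the scanner file: mean signals minus median background by normexp with offset 50, loess within the array with control spots at weight 0, outlier spots (234 of 43376) left out, and spots of a probe averaged, with limma 3.58.1 in R 4.3.3. A gene was the mean of its probes well above background in at least 1 channel. In the HCT116 channel 70.8% of spots were well above background and the median signal was 4.62 times background; in the DKO channel these were 78.6% and 10.3 times. Where 1 channel was not well above background, a fold is given as a bound against the lowest signal called well above background (110 in HCT116 and 116 in DKO) or the dim probe's own signal if higher. List medians with those genes at their bounds were the same to the decimals printed. Where the dim probe's own signal was the higher, the bound is the ordinary ratio. The equal medians therefore do not show how far undetected genes act on the lists. DAC and TSA values, and the DKO values set beside them, came from the deposited table, with a gene as the mean of its probes. Probes were named from the transcript accession for 57.2% of probes, from a current symbol for 2342, from a synonym for 1021 and as in the file for 14203.

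For ChIP, log2 ratios of Agilent processed signals, immunoprecipitated over input, were centred on each array's median. For part 1 of the H3K4me2 arrays the deposited ratios were used for both lines, because the DKO scanner file of that part was not used here. A promoter was the mean of at least 3 probes within 1000 bp of an inferred transcription start. The start was taken as the middle of the gap between a probe annotated as inside the gene and the adjacent promoter probe. That gap was at most 1500 bp, so starts are approximate. Input was well above background at 97.0% to 98.0% of probes and immunoprecipitated DNA at 84.6% to 96.1%, and median signal over background was 4.07 to 6.00 for input and 2.95 to 7.69 for immunoprecipitated DNA, on the 7 arrays with scanner files. A mark was counted at a log2 ratio of at least 1. Gene symbols on these arrays were current for 11794 genes, matched by synonym for 2861 and kept as in the file for 1323.

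No p-value was computed. Genes and promoters were counted at 2-fold (log2 of 1), and 21 gene lists fixed before the data were examined were placed by the percentile of their median among 10000 random lists of the same size, drawn within 10 bins of mean intensity. The lists were genes known for hypermethylation in cancer, cancer-testis, imprinted, HOX, developmental transcription factor, interferon response, antigen presentation, p53 target, histone deacetylase inhibitor response, proliferation, DNA methylation machinery, chromatin machinery, WNT target, intestinal epithelial, mesenchymal, blood cell, neuronal, core histone, ribosomal protein, housekeeping, and stress and heat shock genes. A list median outside the middle 95% of random medians was called above or below. Overlaps of gene sets are given beside the product of their sizes over all genes measured in both. Named genes were chosen by a rule fixed before the data were examined: DNMT1 and DNMT3B; the 8 genes with the largest and the 8 with the smallest value per comparison, with a symbol that is not a clone, LOC, KIAA, FLJ or open reading frame name and without chromosome Y genes and XIST; and up to 4 members of each list with the largest absolute change. Some of the genes the rule gives are printed. Expression values of genes named for their marks, and marks of genes named for their expression, are given where they are set side by side.

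The steps were tested on simulated data. Among 41000 simulated probes with the noise of the expression array, simulated log2 ratios of 1.5 and -1.5 were recovered as 1.34 and -1.23. Of these, 92% and 76% passed 2-fold, while 0% of unchanged probes did. Large ratios were thus shrunken more at the low side in this simulation. All changed probes in it were well above background in HCT116 and only the DKO channel was shifted, so rises from a dim HCT116 signal were not simulated. Simulated promoter differences of 1.25 came back as 1.17 for H3K4me2 and 1.27 for H3K27me3. Of 200 simulated lists without a shift 4.5% fell outside the middle 95%, and of 200 shifted by 0.5 log2 units 99% did. These lists were drawn at random from the same promoters as the random lists. The 4.5% therefore checks the calculation only and does not speak for real lists, whose members may go together. The noise in these simulations is that between spots or neighbouring probes and leaves out culture, immunoprecipitation and hybridisation.

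Alternatives tried were Agilent processed signals, median centring, no background subtraction, the deposited table, other filters on dim probes and other probe summaries for expression; DAC thresholds of 1.5-fold and 3-fold and a TSA threshold of 2-fold for candidates; normexp, the deposited table, scaling to the same median absolute deviation, quantile normalization, all probes of a gene and a filter on dim input for ChIP; and mark thresholds of 0.5 and 1.5. After the data were seen the following were added: the DKO column in its deposited order, the DKO scanner ratio for candidates, differences taken from their median, random lists matched on HCT116 expression, and quantile normalization for classes, candidates and expression. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and the R package data.table (version 1.17.8).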

Results

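HCT116 is an established human colorectal carcinoma line in which many promoter CpG islands carry dense DNA methylation. DKO is a derivative of it in which the DNA methyltransferase genes DNMT1 and DNMT3B were disrupted. The series was built to ask which histone marks lie on genes with hypermethylated promoters, and what becomes of the marks and of expression once DNA methylation is lost. It held 11 array samples in 7 groups. Of these, 3 were expression arrays, each with a treated or DKO RNA in the red channel (Cy5) and a mock-treated or HCT116 RNA in the green channel (Cy3). The first compared HCT116 cells given the DNA methyltransferase inhibitor DAC (decitabine) at 5 µM for 96 h with mock-treated cells. The next compared HCT116 cells given the histone deacetylase inhibitor trichostatin A (TSA) at 300 nM for 18 h with mock-treated cells, and the last compared DKO with HCT116. The other 8 arrays were chromatin immunoprecipitations on promoter tiling arrays (ChIP-chip) for histone H3 dimethylated at lysine 4 (H3K4me2), which lies at active or poised promoters, and for H3 trimethylated at lysine 27 (H3K27me3), the mark set by Polycomb group proteins. Each of the 4 combinations of line and mark had 2 arrays, which were the 2 parts of a promoter set with 0 probe names in common. Each gene and promoter was therefore measured on 1 array per comparison or line, with no replicates, and the small number of arrays limits the precision of every value below. No p-value is given for that reason, and gene lists are placed by the percentile of their median among 10000 random lists of the same size matched on intensity, which describes these arrays alone.

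DKO was first compared with HCT116 by expression. DNMT1 had a log2 ratio of -2.25, 4.76-fold lower in DKO than in HCT116, in the direction its disruption would give. The DNMT3B probe read 0.50, but where it lies relative to the disrupted part of the gene is not known here, so it checks nothing. Among the largest ratios was that of UCHL1, a neuronal ubiquitin hydrolase whose promoter is methylated in many tumours, at 6.17 (72.2-fold). TDRD12, a germline Tudor-domain protein, stood at 5.54, and the cancer-testis genes VCX3A, GAGE12F, VCX and PAGE5 stood at 5.49, 5.42, 5.20 and 5.08. BEX1 stood at 5.22. At the other end lay SH3BGRL at -5.22, the stem cell factor gene KITLG at -4.88, the polyamine acetyltransferase gene SAT1 at -4.62, the epidermal growth factor receptor ligand gene AREG at -4.54 and the cystatin gene CSTA at -4.15. FGF13, WNT16 and EREG were not well above background in DKO, where their signals were at least 21.3-fold, 11.9-fold and 13.8-fold lower than in HCT116. These bounds set the brighter channel against the higher of the dim probe's own signal and the lowest signal well above background, and they are open to dye bias because no dye swap was made. VCX, GAGE, PAGE and MAGE genes belong to families of near-identical members, so their probes may read several of them.

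The interferon response genes were the list with the highest median in DKO. Of 37 measured members, 29 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.84, above all random lists. IFI27 stood at 3.93, the antiviral GTPase gene MX1 at 3.85, IFI44 at 3.49 and IFIT1 at 3.13. Antigen presentation genes had a median of 1.18, with 13 of 23 higher and 1 lower, led by the immunoproteasome genes PSMB8 (3.45) and PSMB9 (2.92) and by HLA-C (2.07) and HLA-B (1.99). Cancer-testis genes, normally silent outside the germline, had a median of 1.49, with 26 of 41 higher and 0 lower. Examples beyond those above were PAGE2 at 4.98 and CTCFL at 4.82. Genes known for hypermethylation in cancer had a median of 1.19, with 22 of 36 higher and 1 lower. Among them were the WNT antagonist gene SFRP1 at 4.99 and the protease inhibitor gene TFPI2, which was not well above background in HCT116 and was at least 20.7-fold higher. Part of that list comes from earlier work on these same lines, so it is not independent evidence of its direction.

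Imprinted genes had a median of 0.56, with 8 of 24 higher and 1 lower. NDN, at least 28.8-fold higher, SNRPN, at least 8.22-fold higher, and SNURF, at 3.37, lie in the same imprinted cluster. Markers of blood cells had a median of 0.88 (8 of 23 higher and 1 lower, with LCK at 2.00 and CD3D at least 10.3-fold higher) and neuronal genes one of 0.40, with 5 of 24 higher and 1 lower and the neurofilament gene NEFH at 5.04. WNT target genes had a median of 0.59, with 5 of 19 higher and 2 lower: DKK1 stood at -3.28 and BMP4 at -3.77. Smaller medians above the middle 95% of random lists were those of proliferation genes (0.30, 5 of 46 higher), stress and heat shock genes (0.31, 6 of 24 higher and 5 lower), genes known to respond to histone deacetylase inhibitors (0.24, 11 of 34 higher and 2 lower), mesenchymal genes (0.24, 8 of 24 higher and 2 lower, with SPARC at 3.48), developmental transcription factors (0.21, 15 of 89 higher and 1 lower) and core histones (0.26, 8 of 33 higher and 2 lower). All of these except proliferation genes lay in the middle 95% under at least 1 other setting, as did WNT targets. Housekeeping genes lay above it too, with a median of 0.32, 6 of 35 higher and 1 lower. The median of ribosomal protein genes was -0.31, with 3 of 57 lower, below all but 0.06% of random lists; it was 0.26 when the array was centred without loess, although still -0.29 from the random lists. The medians of HOX genes (0.095), p53 targets (-0.04), the DNA methylation machinery (0.20), other chromatin machinery (-0.05) and intestinal epithelial genes (0.16) lay in the middle 95% of random lists. Among p53 targets, GDF15 stood at -3.59 and PLK2 at 3.36.

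Over 24247 genes and transcripts, 1760 were at least 2-fold higher in DKO and 886 at least 2-fold lower, so that 66.5% of these were higher. Of the higher ones, 556 were not well above background in HCT116. In the simulation 92% of rises but 76% of falls of 1.5 log2 units passed 2-fold. Its changed probes were all well above background in HCT116 and only the DKO channel was shifted, which pushes falls alone towards the floor. It left out rises from a dim HCT116 signal, so it does not tell whether the processing favours higher genes. The DKO channel was the brighter, with a median of 10.3 times background against 4.62. Part of the excess of higher genes may therefore come from the processing and detection. The standard deviation between spots of the same probe was 0.171 (log2, 264 probes), a technical spread that leaves out culture and hybridisation. With median centring in place of the intensity-dependent loess correction the counts became 2785 and 581 (82.7% higher) and the median of all genes went from 0.03 to 0.17, and with the scanner software's own signals they became 2735 and 1947.

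The DAC array put chemical inhibition of DNA methyltransferases in the parent line beside the genetic loss. Cancer-testis genes had the highest list median, at 2.28, with 36 of 43 at least 2-fold higher and 0 lower. VCX3A stood at 5.91, the transketolase-like gene TKTL1 at 5.85, VCX at 5.80, MAGEA9 at 5.60, PAGE2 at 5.51, and GAGE12F and PAGE5 at 5.48 each. UCHL1 stood at 5.85 and TFPI2 at 5.24. Genes known for hypermethylation in cancer had a median of 0.67, with 19 of 45 higher and 1 lower, and included VIM at 3.88. The p53 target list had a median of 0.75, with 12 of 28 higher and 0 lower, led by TIGAR (3.15), PLK2 (2.52) and the death receptor gene FAS (2.45). Core histone genes had a median of 0.39, with 12 of 33 higher and 4 lower, and H2AC18 stood at 4.10. Interferon response genes had a median of 0.33 (11 of 41 higher, IFI27 at 3.22), imprinted genes one of 0.40 (9 of 26 higher and 1 lower, MEG3 at 2.29), mesenchymal genes one of 0.37 (7 of 30, SPARC at 3.99), blood cell markers one of 0.26 (8 of 29 higher and 1 lower, LCK at 2.25) and developmental transcription factors one of 0.17 (10 of 113, FOXL2 at 2.58).

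Genes with low ratios with DAC were of several kinds. DDIT4, an inhibitor of mTOR signalling, stood at -3.21, PHGDH, which catalyses the committed step of serine synthesis, at -3.18, the stress pseudokinase gene TRIB3 at -3.01 and the cystine transporter gene SLC7A11 at -2.96. LURAP1L stood at -3.10, NIBAN1 at -3.07, KCNQ1 at -2.97 and S100A14 at -2.70, and the lowest value over all transcripts was -3.86. The stress and heat shock list had a median of -0.33, with 8 of 25 lower and 5 higher, and lay in the middle 95% with only probes well above background on the DKO array. HSPA1A, an inducible heat shock protein gene, stood at 3.21. Proliferation genes had a median of -0.57, below all random lists, with 6 of 49 at least 2-fold lower and 3 higher; among the lower were the replication licensing gene CDT1 (-1.38) and CENPF (-1.34). DNMT3B stood at -1.08 and DNMT1 at -0.44. The remaining 10 lists lay in the middle 95% of random lists, although HOX genes lay above it with the median of a gene's probes. In all, 1643 of 30944 genes and transcripts were at least 2-fold higher and 909 lower. These values and those for TSA come from the deposited value table, without background flags.

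With TSA fewer genes were past 2-fold, 614 higher and 549 lower. The oxidoreductase gene DHRS2, known to be induced by deacetylase inhibitors, stood at 4.19 and the WNT antagonist gene DKK1 at 3.87, among values that reached 4.67 over all transcripts. TEX19 stood at 3.64, KRTAP3-1 at 3.55, the histone genes H1-2 and H2BC12 at 3.09 and 3.08, PEG10 at 2.82 and ZCCHC12 at 2.79. The core histone list had a median of 0.42, with 9 of 33 higher and 0 lower, and the deacetylase inhibitor response list one of 0.34, with 6 of 34 higher and 2 lower, including CLU at 2.46. WNT targets had a median of 0.14, with 4 of 22 higher and 1 lower, and BMP4 stood at 2.78; with only probes well above background on the DKO array the list lay in the middle 95%. At the low end were LEMD1 (-3.15), DDIT4 (-2.85), LURAP1L (-2.79), KRCC1 (-2.75), the stress transcription factor gene DDIT3 (-2.69), ANGPTL4 (-2.66), DHRS3 (-2.62) and IL20RB (-2.61), and the stress and heat shock list had a median of -0.27, with 7 of 25 lower and 3 higher. The other 17 lists lay in the middle 95% of random lists. For cancer-testis genes 0 of 43 were 2-fold higher (median 0.08), and for genes hypermethylated in cancer 1 of 45 was and 2 were 2-fold lower (median 0.04). DKK1 and BMP4, high with TSA, were low in DKO, as given above.

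**Figure D1:**
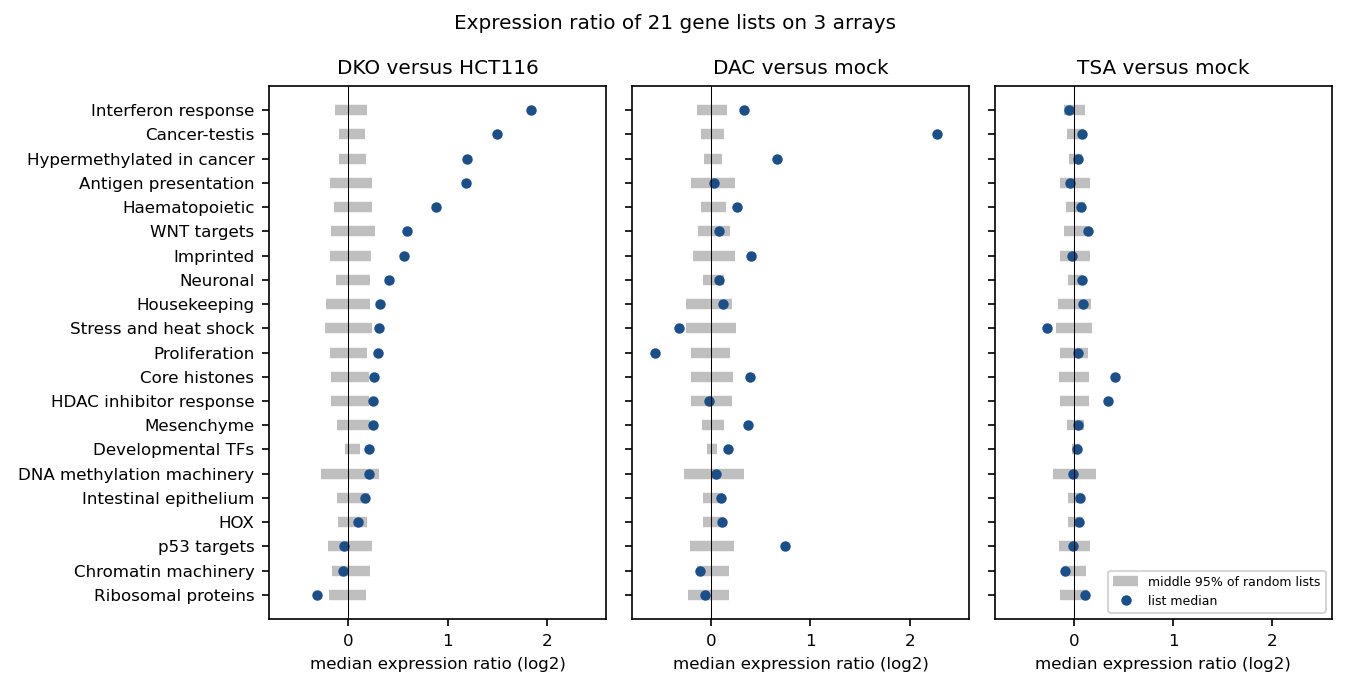
Median log2 expression ratio (horizontal axis) of 21 gene lists (vertical axis) on the arrays of DKO versus HCT116, DAC versus mock and TSA versus mock. Dots are list medians and grey bars hold the middle 95% of medians of matched random lists. Interferon response genes were highest in DKO (1.84), cancer-testis genes highest with DAC (2.28), and core histone genes highest with TSA (0.42). The ribosomal protein dot on the DKO array changes sign when the array is centred without loess.

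Genes higher with DAC and little different with TSA are candidates for silencing by promoter methylation. With the rule of at least 2-fold higher with DAC and a change under 1.4-fold with TSA, 1026 of 30842 genes and transcripts were candidates. They included 30 of 43 cancer-testis genes and 17 of 45 genes known for hypermethylation in cancer, against 3.33% of all genes. Candidates with large DAC ratios included VCX3A, UCHL1, TKTL1, VCX and MAGEA9. In the deposited table, the candidates that were also 2-fold higher in DKO numbered 509, 8.82 times the 57.7 given by independent lists, and by the scanner file of the DKO array 502 of 940 were (7.36 times). VCX3A, UCHL1 and VCX stood at 5.55, 6.23 and 5.24 in the table's DKO column. TKTL1 (0.41) and MAGEA9 (-0.06) did not share that difference. The DKO column of that table had to be moved by 1 row to match its spots, and read as deposited it shared 59 genes, against 62.6 from independent lists.

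DAC and TSA also shared low genes. Both drugs gave ratios at least 2-fold lower for 256 genes, against 16.1 from independent lists, among them DDIT4, TRIB3 and LURAP1L, and 274 genes were low both with DAC and in DKO, against 25.5. Genes high with both drugs numbered 262, against 32.6. Simulated unchanged samples against a shared control gave 0 genes high on both arrays and a covariance of 0.00217 across genes for DAC and TSA, where 0.123 was observed, and 0.00594 for DAC and DKO, where 0.209 was observed. The simulated correlations were 0.497 and 0.508, close to the observed 0.485 and 0.532. They follow from building both simulated arrays on a common control of equal variance, so their closeness decides nothing, and the correlation alone does not separate a shared control from shared differences. The simulation holds spot noise only, which is too small to give 2-fold ratios. Its 0 genes and small covariances therefore do not tell how differences in a shared control RNA or culture would act. Part of each excess may come from shared mock or HCT116 RNA.

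H3K4me2 was then compared between the lines over 15855 promoters, as the mean log2 ratio of immunoprecipitated over input DNA within 1 kb of the transcription start. Named promoters with the largest differences in favour of DKO had carried little of the mark in HCT116. The zinc finger gene ZNF132 went from -1.15 in HCT116 to 2.83 in DKO, the developmental regulator DACH1 from -1.11 to 2.84, the endothelin receptor gene EDNRB from -1.29 to 2.51, NTNG1 from -0.45 to 3.26, the candidate tumour suppressor DLEC1 from -0.94 to 2.77, the neurofilament gene NEFL from -0.67 to 2.96, the homeobox gene MEIS1 from -1.04 to 2.56 and ZNF300 from -0.96 to 2.63. Large differences the other way were at PLA2G3 (3.44 in HCT116 and -0.17 in DKO), GPR162, TNNT1, SCN3A and HAPLN2, with differences of -3.61, -2.65, -2.63, -2.56 and -2.55. CSTA, whose expression ratio was -4.15, differed by -2.41, PAQR7 by -2.35 and COL8A2, whose expression ratio was at least 3.23, by -2.35. DNMT1 carried 2.80 in HCT116 and 2.21 in DKO.

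Among the lists, promoters of genes known for hypermethylation in cancer had the highest median H3K4me2 difference, 1.00, with 22 of 45 higher by at least 1 log2 unit and 1 lower. EYA4 differed by 2.66 and TFPI2 by 2.18. Cancer-testis promoters had a median of 0.76 (11 of 28, with DDX43 at 2.40 and CTCFL at 2.19), HOX promoters one of 0.64 (16 of 38 higher and 3 lower, with HOXB6 at 3.24), developmental transcription factors one of 0.63 (44 of 111 higher and 3 lower, with NKX2-2 at 3.29) and blood cell markers one of 0.27 (7 of 27, with LYZ at 3.05). The medians of mesenchymal genes (0.02, with TWIST1 at 2.32) and neuronal genes (0.01) also lay above the middle 95% of random lists. The lists of p53 targets (-0.81), core histones (-0.76), deacetylase inhibitor response genes (-0.72) and proliferation genes (-0.69) lay below it. Of these 11 lists, the 6 named first, from genes hypermethylated in cancer to mesenchymal genes, lay on the same side under each of 6 other settings, and the other 5 lay in the middle 95% under at least 1. Of these settings, normexp and the deposited ratios changed only part 2 of the array set. Part 1 (7719 of 15855 promoters) already had deposited ratios, so these settings are no alternative for it. Ratios had a narrower range in DKO, which lifts lists low in HCT116, such as blood cell markers (median -0.66). It lowers lists high in HCT116, such as p53 targets (3.20). Quantile normalization, among these settings, gives both lines the same range. The lists were not matched on their HCT116 H3K4me2 level, so what that level adds to each call was not tested. The 24 of 30 mesenchymal genes with an expression value had a median of -0.19 and lay in the middle 95% of random lists matched on HCT116 expression; which of the smaller list and the matching made the difference was not tested. Single members stood apart from their lists. The thioredoxin inhibitor gene TXNIP differed by 2.88, with an expression ratio of 2.79, and the histone genes H3C3 and H1-1 differed by 2.89 and 2.75. Interferon response promoters were mostly marked in both lines and had a median of -0.23 in the middle 95%, but above it under 4 of 6 other settings, and IFIT3 went from -1.08 to 2.05 and XAF1 from -0.49 to 2.00. The other lists in the middle 95% were imprinted genes (-0.38), antigen presentation (-0.71, below it with normexp), DNA methylation machinery (-0.45), chromatin machinery (-0.56), WNT targets (-0.54, above it with all probes of a gene), intestinal epithelium (-0.18, above it under 4 of 6 other settings), ribosomal proteins (-0.60, below it with all probes of a gene), housekeeping genes (-0.67, below it under 3 of 6) and stress genes (-0.60).

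Over all promoters 1486 were higher in H3K4me2 by at least 1 log2 unit in DKO and 1093 lower, and the median difference was -0.50. The balance differed between the parts of the array set. In part 1, with deposited ratios, 769 were higher and 716 lower, and in part 2, with scanner values, 717 and 377. The parts hold different promoters, so these counts alone do not tell source from promoters. Part 1 already had deposited ratios, so the setting with deposited ratios throughout, given below, acted almost only on part 2. The change of balance under it therefore went with the source of part 2. What the different promoters add was not tested. The range of ratios was narrower in DKO (standard deviation 1.39 against 1.78), and the split depended on the processing. It was 1503 higher and 711 lower with both lines scaled to the same median absolute deviation, 1748 and 193 with quantile normalization, which took the median difference to 0.01, and 2447 and 116 with differences taken from their median. The balance turned to fewer higher than lower with the deposited ratios (1392 and 1560), with only probes well above background in the input (1371 and 1569) and with all probes of a gene (719 and 1017). Each line and mark was on its own arrays, so array and line cannot be told apart.

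H3K27me3 was compared in the same way. Large differences in favour of DKO were at the protocadherin genes PCDH17 (-0.72 in HCT116 and 2.07 in DKO) and PCDH7 (-0.55 and 1.80), the imprinted gene NNAT (-0.63 and 1.95), MAB21L1 (-1.05 and 1.36), the LIM homeobox gene ISL2 (-1.47 and 0.78), CD7, MIR424 and ASAP1. Large ones in favour of HCT116 were at GAS2 (1.72 and -1.14), CLEC2B (1.19 and -1.47), GRAP2 (2.42 and -0.18), the olfactory receptor genes OR6C2 (1.47 and -1.09) and OR56A1 (1.95 and -0.57), the meiotic gene TEX15 (2.14 and -0.43), SPINK14 (1.66 and -0.87) and the DNA sensor gene AIM2 (1.66 and -0.87), whose expression ratio was at least 1.92. The median promoter differed by 0.41, so lists are placed against random lists.

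Developmental transcription factors had the highest list median of the H3K27me3 difference, 0.90, with 45 of 111 higher by at least 1 and 0 lower; random lists had a middle 95% of 0.32 to 0.46. TBX3 and MEIS2 differed by 2.01 each and OTX1 by 1.84. Promoters of genes known for hypermethylation in cancer had a median of 0.63 (6 of 45 higher, with TMEFF2 at 1.42), HOX promoters one of 0.60 (9 of 38, with HOXC5 at 1.64) and core histones one of 0.49 (1 of 25). With all probes assigned to a gene in place of the 1 kb window, the hypermethylated list lay -0.027 from its random lists, and with normexp background correction it and the HOX list lay in the middle 95% (0.03 and 0.02 from random lists). Core histones lay in it under 4 of 6 other settings. On the low side, interferon response promoters had a median of 0.03 with 7 of 36 lower, such as OAS1 (-1.93, expression ratio 2.22) and RSAD2 (-1.91). Antigen presentation promoters had a median of -0.16 (4 of 18 lower, with HLA-DMB at -1.58), blood cell markers one of -0.17 (5 of 27 lower and 1 higher, with HBB at -1.87), intestinal epithelial genes one of 0.04 (3 of 33 lower and 2 higher) and cancer-testis genes one of 0.01 (1 of 28 lower, TEX15, and 2 higher), all below the middle 95% of random lists. These 5 lists also lay below it under each of the 6 other settings tried, although their medians changed sign in places, such as 0.32 for antigen presentation with normexp background correction. The other lists lay in the middle 95%, with medians between 0.25 (mesenchymal genes) and 0.55 (imprinted genes, above it under 2 of 6 other settings); with normexp stress genes lay above it and deacetylase inhibitor response genes below.

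Over all promoters 699 were higher in H3K27me3 by at least 1 in DKO and 749 lower. Taken from their median the differences gave 157 higher and 1329 lower, quantile normalization gave 531 and 838 and a median difference of 0.26, normexp background correction gave 637 and 332, and all probes of a gene gave 427 and 915.

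**Figure D2:**
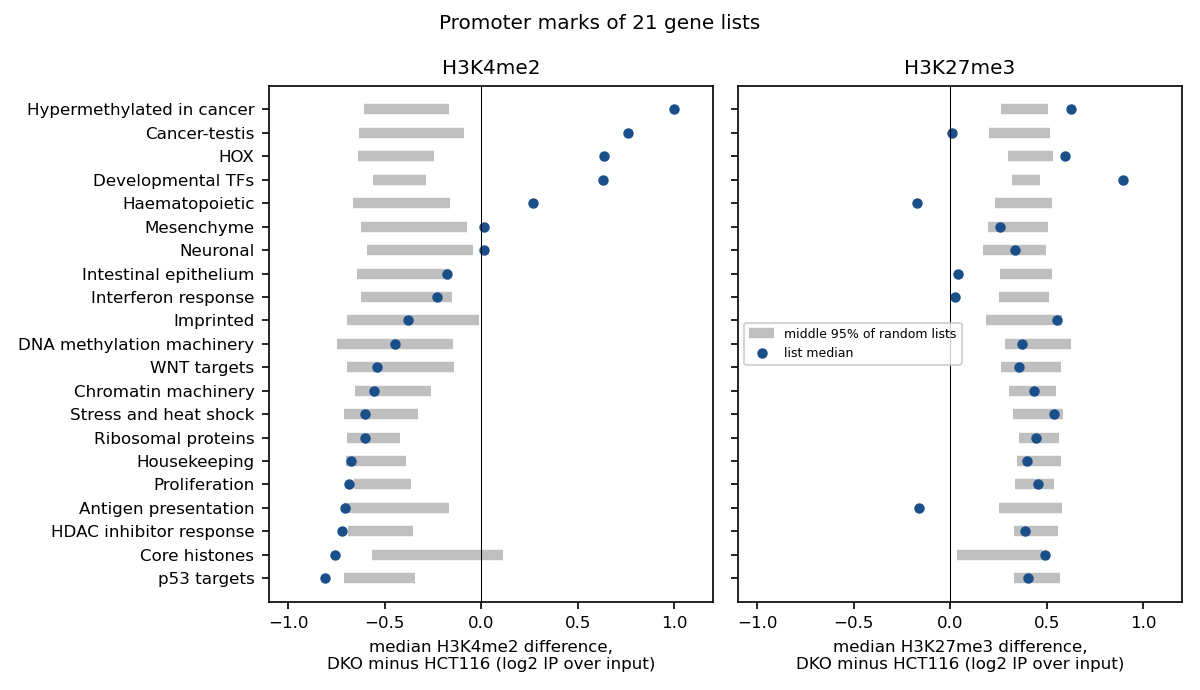
Median difference in promoter H3K4me2 and H3K27me3, DKO minus HCT116 (horizontal axes, log2 immunoprecipitated over input DNA), of 21 gene lists (vertical axis). Dots are list medians and grey bars hold the middle 95% of medians of matched random lists. Genes hypermethylated in cancer, HOX genes and developmental transcription factors lay above the bars for both marks (0.63 to 1.00 for H3K4me2 and 0.60 to 0.90 for H3K27me3), and cancer-testis genes lay above them for H3K4me2 (0.76) and below them for H3K27me3 (0.01). With all probes of a gene, genes hypermethylated in cancer lay -0.027 from random lists in H3K27me3.

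The marks were then joined into promoter classes, a mark being counted at a ratio of at least 1 on the log2 scale. Promoters with both marks numbered 189 in HCT116 and 1269 in DKO. Those with H3K4me2 only numbered 9843 and 9740, those with H3K27me3 only 1551 and 1156, and those with neither 4272 and 3690. Of the promoters with neither mark in HCT116, 648 had H3K4me2 only in DKO, 408 had both, 559 had H3K27me3 only and 2657 had neither. Of those with H3K27me3 only in HCT116, 799 had neither in DKO, 128 both and 88 H3K4me2 only. A further 638 went from H3K4me2 only to both. Among developmental transcription factors, promoters with both marks numbered 2 of 111 in HCT116 and 60 in DKO. Among genes known for hypermethylation in cancer they numbered 0 of 45 and 17, while those with neither numbered 28 and 6. SIX3 and PHOX2A had both marks in DKO and neither in HCT116. Of the interferon response promoters, 5 of 36 carried H3K27me3 in HCT116 and 0 in DKO. Cancer-testis promoters had H3K4me2 only in 3 of 28 in HCT116 and in 9 in DKO, and those with neither numbered 20 and 14. All 36 ribosomal protein promoters had H3K4me2 only in both lines. The class with both marks counted 3813 promoters in DKO and 1100 in HCT116 at a threshold of 0.5, and 176 and 28 at 1.5. Each threshold was the same in both lines, although the median promoter differed by 0.41 in H3K27me3 and by -0.50 in H3K4me2. Part of the differences in class counts may therefore come from that offset.

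**Figure D3:**
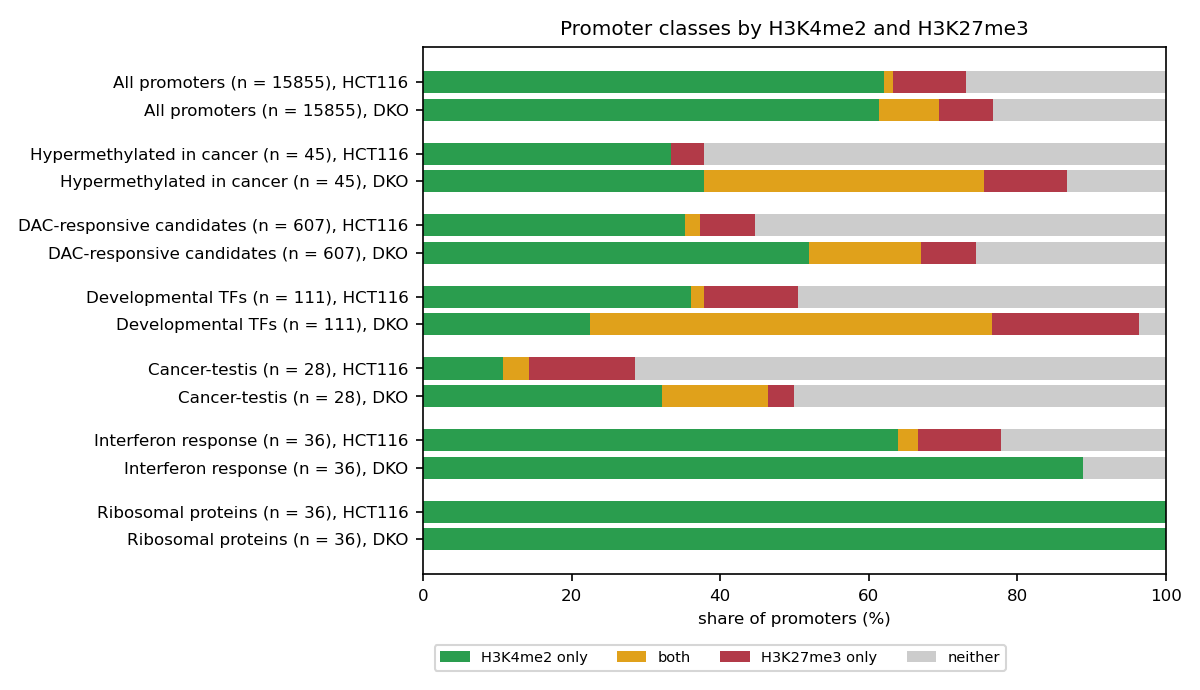
Share of promoters (horizontal axis, percent) with H3K4me2 only, both marks, H3K27me3 only or neither, in HCT116 and in DKO, for all promoters and for 6 gene groups (vertical axis, with the number of promoters). Both marks were found at 54.1% of developmental transcription factor promoters in DKO against 1.80% in HCT116, and at 1269 promoters in DKO against 189 in HCT116 of all 15855. The threshold was the same in both lines, so the shares also hold the difference of the median promoter between them.

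The DAC-responsive candidates address the question in the series title, which pattern of marks goes with hypermethylated genes. In HCT116 the 607 candidates with a measured promoter had a median H3K4me2 ratio of 0.16, -2.08 from random lists, and a median H3K27me3 ratio of 0.11, 0.30 from random lists, and 336 of them had neither mark. In DKO their median H3K4me2 ratio was 1.64 and that of H3K27me3 0.41, 155 had neither mark, and 92 had both, against 12 in HCT116. UCHL1 went from 0.10 to 1.92 in H3K4me2 and from 0.23 to 0.57 in H3K27me3, and TFPI2 from -0.17 to 2.01 and from 0.04 to 1.04. Their median H3K4me2 difference of 0.47 lay above random lists (-0.51 to -0.41) and their median H3K27me3 difference of 0.32 below them (0.36 to 0.42), though within them after quantile normalization. The 286 candidates that were also higher in DKO had a median H3K4me2 difference of 1.08, and the 321 that were not had one of 0.02, which also lay above all random lists (0.50 from their median). Those 321 were low in HCT116 (median H3K4me2 ratio 0.76, against 2.29 in random lists) and were not matched on that level. The 270 of them with an expression value had a median difference of -0.21, 0.26 above lists matched on HCT116 expression. Against random lists matched on HCT116 expression, the H3K4me2 of the 555 candidates with an expression value differed by -1.17 in HCT116 and by 0.0034 in DKO, where all 607 had differed by -0.18 with matching on input signal, and their H3K27me3 in HCT116 stood 0.04 above them, within the middle 95%.

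Marks and expression were set against each other across genes, which are not independent replicates. Genes whose promoters had neither mark in HCT116 and H3K4me2 only in DKO had a median expression ratio of 0.79, and 213 of 497 (42.9%) were at least 2-fold higher in DKO. That share was 17.8% over all measured genes with neither mark in HCT116 and 8.44% over all 12327 measured genes. CTCFL, DDX43 and MAEL, germline genes with expression ratios of 4.82, at least 4.26 and at least 3.12, went from neither mark to H3K4me2 only, with H3K27me3 ratios of 0.00, -0.03 and 0.01 in DKO. Where both marks were found in DKO the median was 0.46, with 92 of 295 (31.2%) higher, as for LEF1 and TFPI2, with ratios of at least 1.86 and 4.37 because neither was well above background in HCT116. The TAC1 and NKX2-2 promoters differed by 2.32 and 3.29 in H3K4me2 without an expression value above background. For promoters with neither mark in both lines the median was 0.04, and for those with H3K4me2 only in both it was 0.02. The 59 measured genes that went from H3K27me3 only to H3K4me2 only had a median of 1.04, with 31 at least 2-fold higher, while the 400 that went from H3K27me3 only to neither had one of 0.08. With the deposited table's DKO values, which hold dim probes too, the medians of 0.79, 0.46 and 1.04 became 0.58, 0.27 and 0.42. Across 12327 genes the expression ratio had a Pearson correlation of 0.35 with the H3K4me2 difference and of -0.14 with the H3K27me3 difference. Of 1005 genes higher in H3K4me2 by at least 1, 358 (35.6%) were 2-fold higher in expression, against 8.44% of all 12327.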

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

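The DKO column in its deposited order, the DKO scanner ratio for candidates, differences taken from their median, random lists matched on HCT116 expression, and quantile normalization for promoter classes, candidates and marks against expression were chosen after the data were seen; the other alternatives were set before. No paired analysis was possible because each line and mark was on 1 array per promoter and no array was repeated, and the planned leave-one-out analyses were not run for the same reason. Where a cause is not named, the cause was not tested.

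Among values answering a comparison, 111 stayed close to the main value under an alternative, 41 moved and 1 reversed; among list values 412 stayed close, 112 moved and 1 reversed, and among values of named genes and counts within lists 2121 stayed close, 276 moved and 2 reversed. As for depth, the median signal over background was 4.62 in HCT116 and 10.3 in DKO on their expression array, and 2.95 to 7.69 for immunoprecipitated DNA on the 7 ChIP arrays with scanner files; the DAC and TSA values come without background values.

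For DKO versus HCT116 expression, Agilent processed signals gave 2735 genes higher and 1947 lower (main values 1760 and 886), and median centring in place of loess gave 2785 and 581. With DAC at 1.5-fold there were 2552 candidates, 778 also higher in DKO, 5.42 times the number from independent lists; at 3-fold there were 409 and 258, as the thresholds make for. In its deposited order the DKO column shared 59 genes with the candidates, 0.94 times that number.

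For H3K4me2, scaling to the same median absolute deviation gave 711 promoters lower in DKO (main 1093), quantile normalization 193, and differences from their median 2447 higher and 116 lower. The balance turned to fewer higher than lower with all probes of a gene (719 and 1017), the deposited ratios (1392 and 1560) and the filter on dim input (1371 and 1569). With all probes CIITA went from -1.24 to 0.0093. For H3K27me3, normexp gave 332 lower (main 749), differences from their median 157 higher and 1329 lower, and all probes of a gene 427 higher and 915 lower, with BOLL going from 1.14 to -0.088 and genes hypermethylated in cancer from 0.23 to -0.027 against random lists.

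At a mark threshold of 0.5, HCT116 had 2546 promoters with H3K27me3 only, 1100 with both marks and 2730 with neither, and DKO 3813 with both and 2451 with neither. At 1.5, HCT116 had 655 with H3K27me3 only and 28 with both, DKO 518 and 176, and 113 went from neither to both. With all probes of a gene, which spread beyond the start, HCT116 had 62 with both and 8459 with neither, DKO 5013 with H3K4me2 only, 242 with both and 11548 with neither, and 69 went from neither to both. Under each of these settings more promoters had both marks in DKO than in HCT116. None of these settings was made to take out the difference of the median promoter between the lines. That difference was 0.41 in H3K27me3 and -0.50 in H3K4me2 with the main values. Classes were also counted with both lines scaled to the same median absolute deviation and after quantile normalization. The latter made that difference smaller for both marks. Those class counts are not given here, so how far the offset acts on the classes is left open.

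Against random lists matched on HCT116 expression, the H3K4me2 of the 555 candidates with an expression value was -1.17 from them in HCT116 (main -2.08) and 0.0034 in DKO (main -0.18), a reversal to near 0. For genes higher both in DKO and with DAC the H3K4me2 difference was 1.32 above random lists (main 0.93). With the deposited table as the source of expression, median ratios were 0.58 for promoters going from neither mark to H3K4me2 only, 0.27 from neither to both and 0.42 from H3K27me3 only to H3K4me2 only (main 0.79, 0.46 and 1.04).

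List medians called above or below the middle 95% of random lists stayed so under each planned setting for 10 of 16 lists in DKO expression, 10 of 11 with DAC, 3 of 4 with TSA, 6 of 11 for H3K4me2 and 6 of 9 for H3K27me3. In DKO expression the exceptions were WNT targets, mesenchymal, core histone, stress, developmental transcription factor and deacetylase inhibitor response genes; with DAC the exception was stress genes and with TSA WNT targets. For H3K4me2 they were proliferation, neuronal, core histone, p53 target and deacetylase inhibitor response genes; interferon and intestinal genes lay above it under 4 of 6 settings other than the main, and housekeeping genes below it under 3. The 24 mesenchymal genes with an expression value lay in the middle 95% of random lists matched on HCT116 expression. For H3K27me3 they were genes hypermethylated in cancer, HOX genes and core histones.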

Other observations

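The gene families below and both tests on the order of the DKO column were chosen after the results were seen; the other tests were set down before their results.

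Some gene families stood out by name, most of them on none of the fixed lists. Olfactory receptor genes, which lie in large clusters and are silent in most tissues, had a median H3K27me3 ratio of 1.04 in HCT116 and -0.23 in DKO, and 120 of 266 promoters were lower in DKO by at least 1 log2 unit. Their median difference was -0.85 (-0.54 with normexp, where 74 were lower), and H3K27me3 only was found at 136 of these promoters in HCT116 and at 24 in DKO. The difference was also -0.84 from lists matched on the HCT116 H3K27me3 level, and their H3K4me2 differed by -0.12. Keratin and keratin-associated protein genes, clustered too, differed by -0.57 in H3K27me3 (14 of 73 lower), and MHC class II genes by -1.07 (7 of 11 lower). With normexp these became -0.26 (3 of 73 lower) and -0.52 (2 of 11 lower). Protocadherin genes went the other way, with median differences of 0.89 in H3K27me3 (15 of 46 higher) and 1.19 in H3K4me2 (26 of 46 higher). With normexp the first became 0.47 (5 of 46 higher), and with all probes of a gene the other became 0.39 (7 of 49 higher). Against lists matched on the HCT116 level of the mark, the H3K27me3 excess of 0.81 over random lists became 0.44.

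On the expression arrays, zinc finger genes of the ZNF family had a median log2 ratio of 0.35 with DAC, with 79 of 435 at least 2-fold higher and 1 lower. Aminoacyl-tRNA synthetase genes, which load tRNAs with their amino acids, had medians of -0.88 with DAC, -0.64 with TSA and -0.41 in DKO, with 6, 6 and 3 of 17 at least 2-fold lower.

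The first pattern weighed was that genes higher with DAC and genes higher in DKO shared no more than independent lists would when the DKO column was read in its deposited order (87 genes, against 100.02 from independent lists). If the column stands 1 row off, spots of the same probe should match once it is moved, and the variance within probes fell to 0.0245 of the total. That DAC and DKO had different high genes is argued against by the scanner file, in which the genes high in both were 5.96 times those of independent lists. The shift of the column is the explanation left, and how it arose is not known here.

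Candidates had higher H3K4me2 ratios in DKO than in HCT116, while the median promoter differed by -0.50 with the main values. The latter difference depended on the processing, as given above, and does not show that the typical promoter lost the mark. A narrower range of ratios in DKO would lift any promoter low in HCT116, but the candidates stood 0.53 above lists matched on their HCT116 H3K4me2. Matched on input signal they stood 0.93 above, so part of that excess goes with the HCT116 level. The narrower range is thus argued against only as the whole of the difference. Scaling of the arrays is argued against too, since they stood 0.62 above matched lists after quantile normalization. A loss of DNA methylation at these promoters may lie behind the difference, but methylation was not measured on these arrays, DKO may differ from HCT116 in other ways as a derived clone, and the lines cannot be told apart from their arrays.

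Developmental transcription factors carried more H3K27me3 in DKO than in HCT116, and cancer-testis promoters did not. A narrower range in DKO lifts promoters low in HCT116, but both lists were high there. Their medians were 0.45 and 0.38, against -0.23 and -0.22 in random lists. The narrower range would thus lower both differences. That developmental transcription factors stood 0.55 above lists matched on the HCT116 H3K27me3 level therefore adds little. Cancer-testis promoters stood -0.35 from such lists, which argues against the narrower range as the whole of their low difference. A trend with the H3K4me2 level in DKO is argued against by lists matched on it, from which the former list differed by 0.45 and cancer-testis promoters by -0.37. A candidate explanation is that Polycomb marks CpG-rich developmental promoters once DNA methylation is gone, while cancer-testis promoters take up no more of it. Their median H3K27me3 ratio was 0.38 in HCT116 and 0.48 in DKO, above random lists matched on input while the 26 of 28 with an expression value lay in the middle 95% of lists matched on HCT116 expression; sequence and methylation were not tested, and clone and array stay confounded with line.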
